A study of Homo sapiens with 18 samples.

How the data were processed

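Small RNA was sequenced from cultured human skin cells: fibroblasts, keratinocytes (the main cell of the epidermis) and melanocytes (the pigment cell of the skin). The labels describe matched cells of the 3 types from 3 donors, each type grown in its own medium. Melanocytes were mock-exposed or given ultraviolet B (UVB) at 10 or 30 mJ/cm2 delivered over 10 s. The protocol names harvests at 0 h and 24 h after exposure, and the hour of each library was not given in the sources used here. The sample titles write the doses as 10J and 30J, and the treatment protocol's unit was used. RNA was isolated with a miRNA isolation kit, and libraries were run on an Illumina HiSeq 2500.

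The deposited data were 2 tables of miRNA hairpins, each with 9 libraries. The UVB table held mock, UVB 10 and UVB 30 melanocytes, and the cell-type table held fibroblasts, keratinocytes and untreated melanocytes, with 3 libraries per group and 18 libraries in all. Values deposited by the authors were in RPM, that is reads of a hairpin per 1000000 reads assigned to the listed hairpins of the same library. This unit was read from the values, since every column added up to 1000000. Each table listed 1871 hairpin entries with 1870 distinct names, and 1 name appeared in 2 entries. The submitters' processing notes named FastQC, RSEM and build hg19. Their versions, the aligner, adapter trimming and the miRNA annotation release were not given in the sources used here. RSEM can divide reads that match several hairpins among them, but the values here were whole reads, so how such reads were assigned is not known. Near-identical copies (such as hsa-mir-199a-1 and hsa-mir-199a-2, or the hsa-let-7a hairpins) therefore do not have separately certain levels.

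Every value above 0 was a whole multiple of the smallest value above 0 in its library, within a tolerance of 1e-04, so the read count behind each value was recovered by taking that smallest value as 1 read. Library totals came from the same step. Intervals were exact Poisson or binomial intervals at 95%, and the level that 0 reads allows was taken as 3 reads, per library or over the summed reads of a group as stated. PCR copies of a molecule are not independent, so these intervals and limits cover counting error only. The repeated entry held 0 in every library and was left out.

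Because the tables held normalized values, the test was the one set for such values before the data were examined: limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(RPM + 1) without further normalization. The 9 libraries of a table were fitted together with the group as the only term. Hairpins with at least 1 RPM in at least 3 libraries were tested, 406 in the UVB table and 392 in the cell-type table. Tests were two-sided, and a call needed a Benjamini-Hochberg adjusted p under 0.05. The added 1 RPM shrinks the log2 fold change of hairpins near or under 1 RPM. The counts of calls, 6 contrasts, enrichment in a cell type (higher in both of its contrasts), the miRNA lists and the rule for named hairpins were also set before the data were examined. Replicate spread is given as the SD over n = 3 libraries unless stated.

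Named hairpins were, per contrast, the 8 higher and 8 lower calls with the largest absolute log2 fold change among those with groups that did not overlap and a mean in the higher group of at least the median of that mean. Up to 4 members with the smallest p were added from each list. Where fewer than 5 hairpins passed, the 5 with the smallest p in each direction were taken as values. Host genes and chromosomes came from GENCODE 29 on GRCh38 by miRNA name, which matched 1848 of 1870 hairpin names (98.8%). The authors' build was hg19, so no coordinates are given.

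The 8 miRNA lists covered p53 and DNA damage miRNAs, melanocyte miRNAs, keratinocyte and epithelial miRNAs, fibroblast and mesenchymal miRNAs, the miR-17-92 family, let-7 and miR-98, the imprinted miRNAs of chromosome 14 (14q32), and blood and endothelial miRNAs. Each was tested with camera (limma) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, where at least 5 members were tested, with adjustment over the lists of a contrast. The 14q32 list had 3 tested members in the UVB libraries and so no set test there. Members were also counted with p adjusted over the list alone. Lists of long RNAs set at the same time had no members in the tables.

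Alternatives set before the data were examined were the replicate block, leaving out each library, only the 2 groups compared, no filter, a filter of 5 RPM, a pseudocount of 0.1 RPM, quantile normalization, TMM scaling and limma without trend. Alternatives chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) and DESeq2 1.42.0 on recovered reads, edgeR with the replicate block, a filter on hairpins worth 3 reads in the shallowest library, the UVB table without its 3 libraries of under 10000 reads, mock melanocytes 1 and 2 in place of the untreated melanocytes, the cell-type table without keratinocytes 2 and 3, and keratinocytes 2 and 3 thinned to the reads of keratinocyte 1. The use of mock melanocytes crosses the 2 tables, with each library scaled to its own 1000000 reads. Replicate numbers were taken to pair the libraries by donor, from the labels' account of matched donors. In the UVB table same-numbered libraries deviated together, with correlations of deviations from the group means of 0.103 to 0.335. Among the 6 deep UVB libraries the reads of same-numbered libraries differed less, with a chi-square per degree of freedom over hairpins of 12.5 to 62.4. It was 133 to 510 between libraries of different numbers. The fits to the deep UVB libraries had the group as the only term and did not use the pairing. In the cell-type table these correlations were -0.154 to 0.0546. No sequencing batch was given in the labels.

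The tests were tried on simulated data with real depths, in 10 draws with 200 changed hairpins each. For 8-fold changes edgeR recovered 63.6%, 77.1% and 74.3% in UVB 10 against mock, UVB 30 against mock and UVB 30 against UVB 10, and limma recovered 15.5%, 13.7% and 15.0%. For melanocytes against fibroblasts and against keratinocytes edgeR recovered 8.05% and 6.66%, and limma 47.8% and 30.7%. In those contrasts 48.4% and 44.8% of the limma calls were on simulated hairpins that had not been changed (4.30% and 10.6% with edgeR). In the UVB contrasts, in the same order, this share was 14.8%, 22.5% and 23.1% with limma and 6.32%, 6.63% and 6.22% with edgeR. For keratinocytes against fibroblasts edgeR recovered 58.6% and limma 44.7%, with 2.43% and 28.5% of calls on unchanged hairpins. For 2-fold changes in the UVB contrasts, in the same order, edgeR recovered 23.8%, 39.0% and 29.7%, and limma 3.14%, 2.61% and 3.79%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.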

Results

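Hairpin-level miRNA abundance was measured in 18 small RNA libraries of cultured human skin cells, 3 libraries in each of 6 groups. The UVB table held mock-exposed melanocytes and melanocytes given UVB at 10 or 30 mJ/cm2. The cell-type table held fibroblasts, keratinocytes and untreated melanocytes.

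Sequencing depth ran from 512 to 3617235 reads per library. Mock melanocytes 1, 2 and 3 held 1060966, 3454201 and 1675 reads assigned to hairpins, UVB 10 melanocytes 9684, 3514353 and 1259, and UVB 30 melanocytes 3611429, 2169250 and 1663961. Fibroblasts held 1881352, 2375657 and 673817 reads, and keratinocytes 29066, 1338457 and 3617235. Untreated melanocytes held 1126, 512 and 1792 reads, so that 1 read equalled 888, 1953 and 558 RPM. In the 3 untreated melanocyte libraries together (3430 reads), 0 reads allows a level of up to 875 RPM, and 275 of the 392 tested hairpins had 0 reads in all 3. The same limit was 0.664 RPM in mock, 0.851 RPM in UVB 10, 0.403 RPM in UVB 30, 0.608 RPM in fibroblasts and 0.602 RPM in keratinocytes. The tests with edgeR and DESeq2, with mock melanocytes in place of untreated ones, without keratinocytes 2 and 3, and in the deep UVB libraries alone were chosen after the results were seen.

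**Figure D1:**
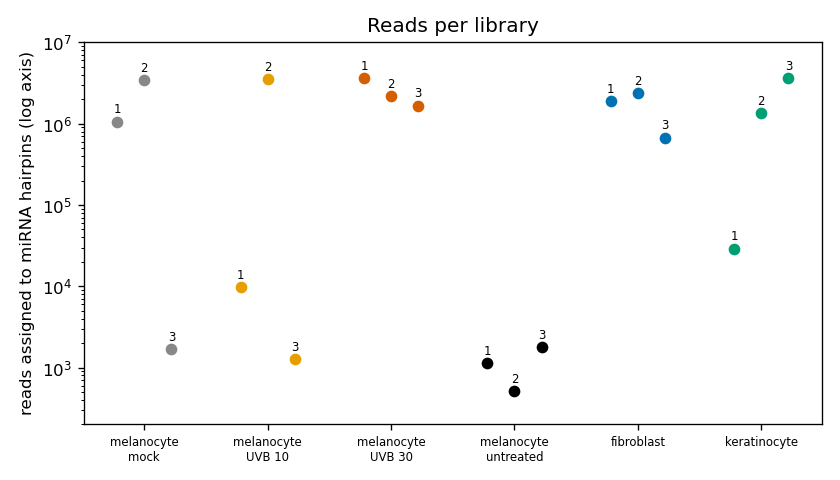
Reads assigned to miRNA hairpins in each of the 18 libraries, by group on the x axis and on a log axis in y, with the replicate number beside each point. The 3 untreated melanocyte libraries lie between 512 and 1792 reads, and mock 3, UVB 10 replicates 1 and 3 lie below 10000 reads.

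Untreated melanocytes were compared with fibroblasts to find miRNAs that differ between pigment cells and dermal cells. The melanocyte profile was led by hsa-mir-10b, hsa-mir-22 and hsa-mir-146a, and 13 hairpins were higher than in fibroblasts. Hsa-mir-211, which lies in an intron of the melanocyte gene TRPM1 on chromosome 15, averaged 7915 ± 5755 RPM (SD, n = 3, 34 reads) against 12.7 ± 17.9 RPM in fibroblasts, 621 times as much. That ratio rested on fibroblast 2 (33.3 RPM, against 0.532 and 4.45 RPM in fibroblasts 1 and 3), as it was 3176 without it, and it was 362 without melanocyte 3. Hsa-mir-146a, known for restraining innate immune signalling and lying in an exon of MIR3142HG on chromosome 5, averaged 69844 ± 41086 against 161 ± 115 RPM, a 433-fold difference (286-fold without melanocyte 3 and 690-fold without fibroblast 2). Hsa-mir-508, part of a miRNA cluster on chromosome X, averaged 1987 ± 229.9 RPM (7 reads) against 0.982 ± 1.7 RPM (7 reads). Fibroblasts were led by hsa-mir-143, a miRNA of smooth muscle and other mesenchymal cells in an exon of CARMN, at 190128 ± 25104 RPM against 22611 ± 27158 RPM in melanocytes, which did not pass the test (log2 fold change -7.67, adjusted p = 0.119).

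Among the other hairpins higher in melanocytes, hsa-mir-10a, in an exon of HOXB4 on chromosome 17, had a log2 fold change of 7.48 (SE 0.97, adjusted p = 0.000427). Hsa-mir-378a, in an intron of PPARGC1B, had 6.96 (SE 0.87, adjusted p = 0.000337) with 17 melanocyte reads. Hsa-mir-10b, in an intron of HOXD3 on chromosome 2, averaged 203967 ± 123070 against 18821 ± 7385 RPM, a 10.8-fold difference (7.12-fold without melanocyte 3; adjusted p = 0.00535). Hsa-mir-30d and hsa-mir-25, the latter in an intron of MCM7, were 4.89 and 4.36 times as high (adjusted p = 0.00213 and 0.00846). Fitted log2 fold changes were 10.29 for hsa-mir-508, 9.99 for hsa-mir-211 and 8.91 for hsa-mir-146a, with adjusted p of 0.00169, 0.00929 and 0.000943.

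In the other direction 209 hairpins were lower in melanocytes, of which 202 had 0 reads in all 3 melanocyte libraries. For 199 of those 202 the fibroblast mean itself was under the 875 RPM that 0 reads allows, so a difference was not detectable at this depth. The remaining 3 gave a bound over the group: hsa-mir-23b (2063 ± 330.4 RPM in fibroblasts) was at least 2.36-fold lower, the hypoxia-induced hsa-mir-210 (1499 ± 176 RPM) at least 1.71-fold and hsa-mir-424 (1038 ± 158 RPM) at least 1.19-fold. Hairpins with 0 melanocyte reads and fibroblast means under the limit included hsa-mir-196a-2 (792 ± 443 RPM), hsa-mir-214 (657 ± 82.2 RPM), hsa-mir-493 (522 ± 97.6 RPM), hsa-mir-145 (513 ± 81.0 RPM) and hsa-mir-192 (457 ± 97.5 RPM). Of the 7 lower hairpins with melanocyte reads, hsa-mir-27b averaged 16151 ± 8211 against 68274 ± 20799 RPM, 4.23 times less (adjusted p = 0.00803). Hsa-let-7a-1 averaged 8034 ± 3069.8 against 15889 ± 3003 RPM (adjusted p = 0.0376), and that call was lost without fibroblast 1, fibroblast 3, keratinocyte 2, melanocyte 2 or melanocyte 3, with adjusted p of 0.0859, 0.103, 0.0511, 0.0960 and 0.0790 in that order.

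By list, 4 of 15 tested melanocyte miRNAs were higher than in fibroblasts and 2 lower (4 and 2 when adjusted over the list alone). Camera placed this list up (adjusted p = 1.08e-05), and the adjusted p was 0.0635 with an estimated correlation. Its median log2 fold change was -0.39 and its mean 1.69, and the median was 5.29 with members at 0 reads set to the limit of 3 reads. The 2 lower members, hsa-mir-137 and hsa-mir-330, had 0 melanocyte reads and fibroblast means under the depth limit. All 34 members of the 14q32 list that were called lower of 45 tested (39 adjusted over the list alone) had 0 melanocyte reads, and camera placed the list down (adjusted p = 0.0123, and adjusted p = 0.743 with an estimated correlation). Its median was -5.01 as fitted and 4.35 at the limit, so untreated melanocytes did not settle its direction. Of 25 fibroblast and mesenchymal miRNAs 16 were lower, 15 of them at 0 reads, and 2 were higher (17 and 2 adjusted over the list alone; camera adjusted p = 0.264). The 2 higher members were hsa-mir-10a and hsa-mir-10b, which lie among the HOX genes. Among let-7 and miR-98 hairpins 1 of 12 was lower (0 adjusted over the list alone, and 0 over all hairpins by edgeR), and camera placed the list up (adjusted p = 0.00863, and adjusted p = 0.516 with an estimated correlation) while its median and mean were -0.11 and -1.21.

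The p53 and DNA damage list had 1 higher and 12 lower members of 26 (0 and 9 adjusted over the list alone), 11 of the lower at 0 reads. The keratinocyte and epithelial list had 4 lower of 17 (4 over the list alone), the miR-17-92 family 1 higher, hsa-mir-25, and 4 lower of 11 (1 and 4), and the blood and endothelial list 3 lower of 5 (3). Camera called none of these 4 lists (adjusted p = 0.817, 0.376, 0.376 and 0.397). The first 3 had a test direction of up with a negative median and mean. Medians of the p53, keratinocyte, fibroblast, miR-17-92 and blood lists were -3.40, -2.20, -6.14, -3.23 and -5.77 as fitted and 0.85, 6.95, 1.12, 1.34 and 2.49 with members at 0 reads set to the limit.

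The edgeR test on recovered reads called 2 hairpins higher, hsa-mir-378a (adjusted p = 0.0191) and hsa-mir-10a (adjusted p = 0.0207), and 0 lower of 242 tested, with 40 at an unadjusted p under 0.05, and DESeq2 called 25 and 6. The DESeq2 median log2 fold change over hairpins was 5.05, opposite in sign to that of limma (-2.83). Limma had 242 hairpins at an unadjusted p under 0.05, and group values did not overlap for 268 hairpins (68.4%, against 10% by chance). A hairpin with 0 reads in all 3 melanocyte libraries, as 275 of 392 had, cannot overlap where every fibroblast library has reads. That share therefore follows from depth and does not measure separation of the cell types. With mock melanocytes 1 and 2 in place of the untreated libraries, all 13 higher hairpins were called higher again by limma and 12 by edgeR. Of the 209 lower ones 120 had the same sign by limma, 55 were called lower (80 by edgeR) and 19 were called higher (32 by edgeR). Quantile normalization moved the median log2 fold change of all hairpins from -2.83 to 0.00 and gave 103 higher and 80 lower calls.

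**Figure D2:**
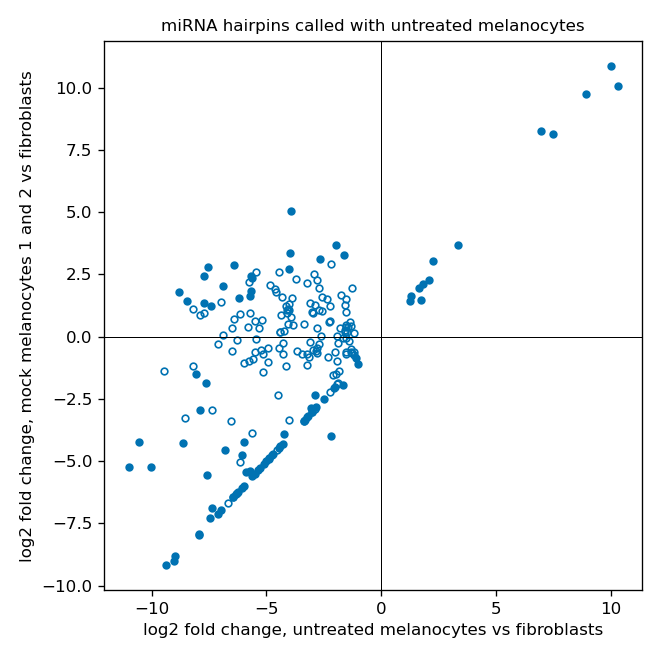
Log2 fold change against fibroblasts of the 222 hairpins called with untreated melanocytes, with untreated melanocytes on the x axis and mock melanocytes 1 and 2 on the y axis; filled points were also called with mock melanocytes. All 13 hairpins right of 0 lie above 0, and of the 209 left of 0, 89 lie above 0.

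Against mock melanocytes 1 and 2, a comparison across the 2 tables chosen after seeing the data, the depth allowed levels under 875 RPM to be read. Hsa-mir-211 averaged 12273 RPM, hsa-mir-146a 112803 RPM and hsa-mir-10a 69410 RPM there. Hsa-mir-23b, hsa-mir-210 and hsa-mir-424 stood at 53.4, 80.9 and 26.1 RPM, with log2 fold changes of -5.23, -4.25 and -5.25 against fibroblasts (adjusted p = 0.00065, 0.00102 and 2.51e-05). Hsa-mir-214 and hsa-mir-145, mesenchymal miRNAs, had 1 read each, and hsa-mir-493 of the 14q32 cluster had 0 reads in the 2 libraries (adjusted p = 0.000318, 0.00475 and 4.84e-05). Hsa-mir-143, at 7.54 and 6.66 RPM in the 2 libraries, was called lower (log2 fold change -14.51, adjusted p = 0.000178). Hsa-mir-27b was lower again at 4168 RPM (adjusted p = 0.000111). In contrast hsa-mir-192 averaged 1575 RPM and was higher than in fibroblasts (log2 fold change 1.80, adjusted p = 0.0188), as were hsa-mir-93 (2.81, adjusted p = 0.0132) and hsa-mir-106b (1.24, adjusted p = 0.0452), which share the MCM7 intron with hsa-mir-25. By edgeR the adjusted p was 0.0471, 0.0167 and 0.0766, so the call of hsa-mir-106b ended there. In this comparison 33 of 45 14q32 members were lower (median log2 fold change -5.36, camera adjusted p = 5.92e-19, and adjusted p = 0.268 with an estimated correlation). Of 25 fibroblast miRNAs 14 were lower and 2 higher, and 7 of 11 miR-17-92 family members were higher (camera adjusted p = 1.89e-05 and 0.00259, both 0.268 as adjusted p with an estimated correlation).

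Untreated melanocytes were next compared with keratinocytes, the other epidermal cell type. Hsa-mir-211, hsa-mir-508 and hsa-mir-146a were again higher in melanocytes, at 40.3, 42.6 and 21.3 times the keratinocyte means of 196 ± 337, 46.6 ± 78.8 and 3281 ± 4996 RPM. Hsa-mir-30d and hsa-mir-25 were 3.1 and 3.18 times as high. The ratios of the first 3 rested on keratinocyte 1 and were 3945, 1773 and 176 without it. Some epithelial miRNAs had no melanocyte reads: hsa-mir-205, a miRNA of stratified epithelia in an exon of MIR205HG on chromosome 1, averaged 23052 ± 39388 RPM in keratinocytes and was at least 26.4-fold lower in melanocytes. Hsa-mir-203a, which promotes keratinocyte differentiation, was at least 12.9-fold lower (11323 ± 19423 RPM in keratinocytes), and hsa-mir-182 at least 9.29-fold (8128 ± 13728 RPM). These keratinocyte means rested mainly on keratinocyte 1, as the SDs show, so the bounds are for the group mean and not for each library. In keratinocytes 2 and 3 hsa-mir-205 stood at 290 and 334 RPM, under the limit of 875 RPM.

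Adjusted p was 0.0205 for hsa-mir-211 (log2 fold change 8.78, SE 2.25), 0.00702 for hsa-mir-508 (8.01, SE 1.68), 0.0105 for hsa-mir-146a (5.83, SE 1.31), 0.0127 for hsa-mir-30d and 0.0331 for hsa-mir-25. These were the 5 higher calls. Of the 93 lower calls 92 had 0 melanocyte reads, and for 85 of these the keratinocyte mean was under the 875 RPM that 0 reads allows. Bounds over the group were at least 1.65-fold for hsa-mir-192 (1445 ± 866 RPM in keratinocytes), 1.19-fold for hsa-mir-30c-2 (1044 ± 187 RPM) and 1.09-fold for hsa-mir-23b (954 ± 906 RPM, an SD near the mean). The first 2 did not hold in mock melanocytes 1 and 2, at 1575 and 981 RPM. Limma log2 fold changes were 0.28 and -0.11 there (adjusted p = 0.705 and 0.851), while hsa-mir-23b was lower (-3.71, adjusted p = 0.00466). Hsa-mir-424 (858 ± 190.1 RPM) and hsa-mir-193b (625 ± 234 RPM) lay under the limit. The lower call with melanocyte reads was hsa-let-7a-1, 3.56 times less (log2 fold change -1.88, adjusted p = 0.00357).

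Melanocyte miRNAs had 3 higher and 2 lower members of 15 (3 and 2 adjusted over the list alone), and camera placed the list up (adjusted p = 0.000246, and adjusted p = 0.123 with an estimated correlation). Its median was -0.76 and its mean 0.62, and the median was 4.22 with members at 0 reads set to the limit. The keratinocyte and epithelial list had 10 lower members of 17, all at 0 melanocyte reads (13 adjusted over the list alone). Lower members, all at 0 reads, numbered 9 of 26 for p53 and DNA damage (10 over the list alone), 9 of 25 for fibroblast and mesenchymal miRNAs (14 lower and 2 higher over the list alone), 11 of 45 for 14q32 (11) and 3 of 5 for blood and endothelial miRNAs (3). The miR-17-92 family had 1 higher and 3 lower of 11 (1 and 3), and let-7 and miR-98 had 1 lower of 12 (1). Camera called none of these 7 lists, with adjusted p of 0.139 to 0.648, and the miR-17-92 and let-7 lists had a test direction of up with negative medians. Medians of the p53, keratinocyte, fibroblast, miR-17-92, let-7, 14q32 and blood lists were -4.08, -5.92, -4.04, -3.39, -0.84, -4.21 and -4.83 as fitted and -0.78, -0.12, 2.09, 0.41, -0.84, 4.35 and 2.73 at the limit. Without keratinocyte 1 the number of called lists was 3 in place of 1.

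The edgeR test called 0 of 242 hairpins, with 25 at an unadjusted p under 0.05 and a smallest adjusted p of 0.146, against 209 at an unadjusted p under 0.05 by limma, and DESeq2 called 2 higher and 1 lower. The DESeq2 median log2 fold change over hairpins was 5.04, opposite in sign to that of limma (-2.69). Groups did not overlap for 119 hairpins (30.4%, against 10% by chance), a share that the 275 hairpins at 0 melanocyte reads raise by depth. With the replicate block 3 hairpins were higher. The 5 higher calls became 9 without keratinocyte 1, 3 without keratinocyte 2 or 3, 9 without melanocyte 1 and 8 without melanocyte 2, and the 93 lower calls became 246 without keratinocyte 1. Hsa-mir-211 lost its call without keratinocyte 2, keratinocyte 3 or melanocyte 3 (adjusted p = 0.0781, 0.0698 and 0.0587), and hsa-mir-25 without any 1 of the fibroblasts, keratinocyte 2 or keratinocyte 3 (adjusted p = 0.0554 to 0.122). Without keratinocytes 2 and 3 together, as chosen after seeing the data, 4 of the 5 higher calls and that of hsa-let-7a-1 ended. Log2 fold changes were then 3.52 for hsa-mir-211, 2.80 for hsa-mir-146a, 1.08 for hsa-mir-30d, 1.36 for hsa-mir-25 and -1.64 for hsa-let-7a-1 (adjusted p = 0.438, 0.207, 0.210, 0.424 and 0.0697). With mock melanocytes 1 and 2 the 5 higher hairpins were called again by limma and 4 of them by edgeR, where hsa-mir-211 had an adjusted p of 0.0681. By limma hsa-mir-205 had 0 reads (adjusted p = 0.0074), 28 of the 93 lower hairpins were called lower (39 by edgeR), 8 were called higher (16 by edgeR), and hsa-mir-192 had a log2 fold change of 0.28 (adjusted p = 0.705). Hsa-mir-203a and hsa-mir-182 averaged 10.1 and 35.4 RPM in mock melanocytes 1 and 2. Limma did not call them lower than in keratinocytes (adjusted p = 0.0967 and 0.121), while edgeR did (adjusted p = 0.0241 and 0.0315). Quantile normalization moved the median log2 fold change from -2.69 to -0.05.

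**Figure D3:**
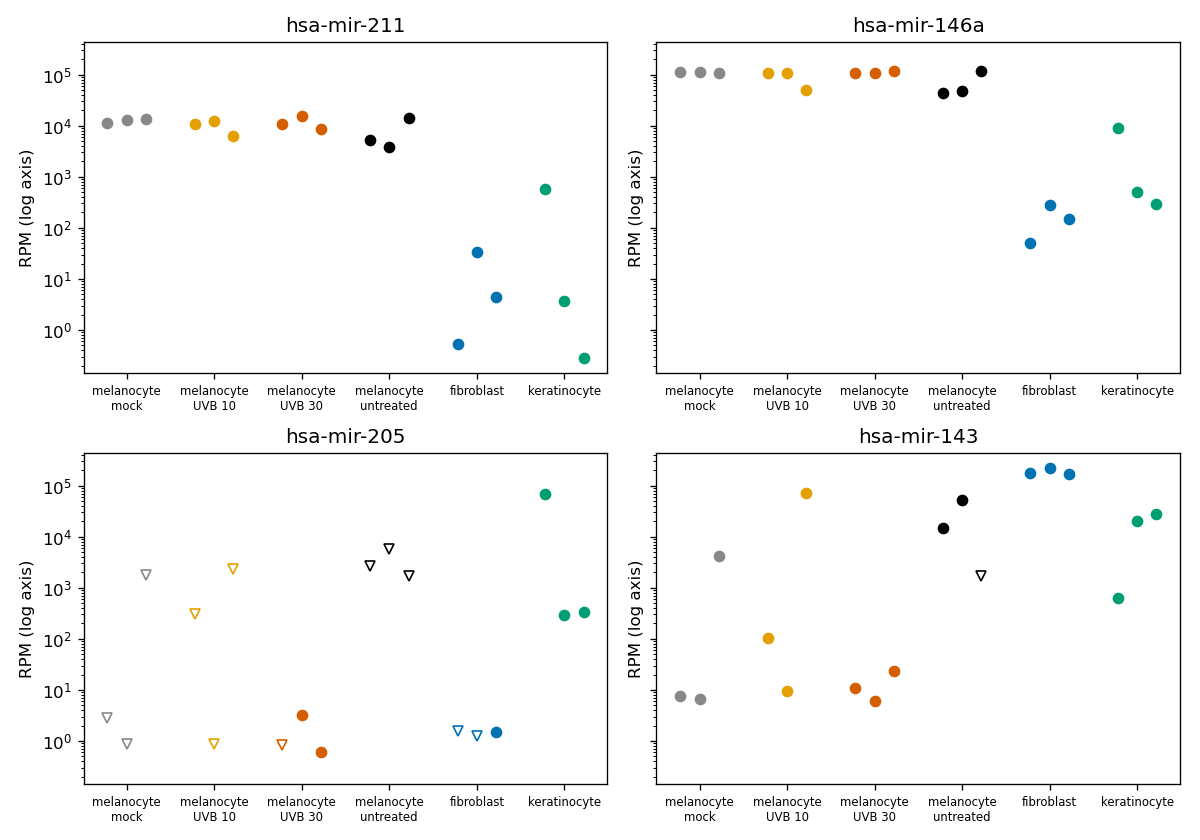
RPM (log axis) of hsa-mir-211, hsa-mir-146a, hsa-mir-205 and hsa-mir-143 in each of the 18 libraries, by group; open triangles mark libraries with 0 reads, drawn at the level of 3 reads. Hsa-mir-211 lies at 3906 RPM or more in every melanocyte library and at 585 RPM or less in fibroblasts and keratinocytes, and hsa-mir-205 is highest in keratinocyte 1.

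Keratinocytes were compared with fibroblasts, the pair of cell types with the deeper libraries. Keratinocytes carried the epithelial hsa-mir-205 at 68534, 289.9 and 334 RPM in libraries 1, 2 and 3, against 0, 0 and 1.48 RPM in fibroblasts. Hsa-mir-891a, of a chromosome X cluster, averaged 172 ± 163 against 0.495 ± 0.857 RPM, and hsa-mir-29c, which represses collagen genes, 74.1 ± 5.41 against 16.9 ± 2.09 RPM (4.39-fold). Hsa-mir-378a and hsa-mir-10a were 36.9 and 38.7 times as high in keratinocytes. The hypoxia-induced hsa-mir-210, in an intron of MIR210HG on chromosome 11, was 7.73 times lower in keratinocytes (194 ± 159.8 against 1499 ± 176 RPM). Without keratinocyte 1 the ratios were 16.6 for hsa-mir-378a, 15.1 for hsa-mir-10a and 14.8 for hsa-mir-210.

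Of 392 hairpins 11 were higher and 3 lower. Adjusted p was 0.0263 for hsa-mir-205 (log2 fold change 10.44, SE 1.93), 0.0213 for hsa-mir-891a (6.27, SE 0.96), 0.0257 for hsa-mir-378a, 0.0495 for hsa-mir-10a, 0.0243 for hsa-mir-29c and 0.0412 for hsa-mir-210 (-3.23). Hsa-mir-6087 (4.91-fold, adjusted p = 0.0263) and the abundant hsa-mir-191, in an intron of DALRD3 (2.92-fold, adjusted p = 0.0213), were also higher, as was hsa-mir-184 (45.9 ± 49.7 against 0.635 ± 0.561 RPM, adjusted p = 0.0213). The mesenchymal hsa-mir-143 and hsa-mir-145 averaged 16463 ± 14173 and 43.9 ± 38.8 RPM in keratinocytes against 190128 ± 25104 and 513 ± 81.0 RPM in fibroblasts and did not pass (adjusted p = 0.605 and 0.207), while edgeR called hsa-mir-145 lower (adjusted p = 0.0216). Hsa-mir-182 and hsa-mir-141, an epithelial miRNA of the miR-200 family, did not pass either, with log2 fold changes of 7.06 and 5.92 (adjusted p = 0.101 and 0.128).

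The keratinocyte and epithelial list had 2 higher members of 17 (6 adjusted over the list alone) with a median log2 fold change of 3.53, and camera placed it up (adjusted p = 0.00481, and adjusted p = 0.516 with an estimated correlation). The fibroblast and mesenchymal list was placed down (adjusted p = 0.00481, and 0.516 as adjusted p with an estimated correlation; median -1.48) although its 1 called member of 25, hsa-mir-10a, was higher (1 over the list alone). The 14q32 list was placed down (adjusted p = 0.0408, and adjusted p = 0.601 with an estimated correlation; median -0.55) and the p53 and DNA damage list up (adjusted p = 0.0488, and adjusted p = 0.516 with an estimated correlation; median 0.57). Of these, 0 of 45 14q32 members passed (0 over the list alone; 0 by edgeR), and 1 of 26 p53 and DNA damage members, hsa-mir-29c, was higher (1). The melanocyte list had 1 higher of 15 (1 over the list alone), and 0 members passed, by limma over all hairpins or over the list alone and by edgeR over all hairpins, in the miR-17-92, let-7 and blood lists of 11, 12 and 5 members. Camera called none of these 4 lists (adjusted p = 0.0789, 0.323, 0.0789 and 0.431). The count of 4 called lists became 2 without fibroblast 2, 1 without keratinocyte 1 and 6 without keratinocyte 2, and the 14q32 direction turned to up without keratinocyte 1 (adjusted p = 0.630).

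The calls rested on few libraries. The 11 higher calls became 1, 0 and 3 without fibroblast 1, 2 or 3, 38 without keratinocyte 1, 0 without keratinocyte 2, and 0 and 7 without melanocyte 2 or 3, and the 3 lower calls became 10 without keratinocyte 1 and 1 or 0 without any 1 of the fibroblasts, keratinocyte 2 or any 1 of the melanocytes. The paired fit with the replicate block called 1 higher and 0 lower. The edgeR test called 9 higher and 4 lower, and DESeq2 11 and 9; limma had 49 hairpins at an unadjusted p under 0.05, and groups did not overlap for 94 (24.0%, against 10% by chance). Keratinocytes 2 and 3 ranked hairpins like fibroblasts (Spearman's rho across hairpins, which are not independent replicates, of 0.912 to 0.914 and 0.916 to 0.923). Keratinocyte 1, with 29066 reads, had 0.661 to 0.685 with fibroblasts and 0.761 and 0.740 with keratinocytes 2 and 3, which cover depth as well as profile. When keratinocytes 2 and 3 were thinned at random to 29066 reads, their rho with fibroblasts was 0.820 to 0.887 over 100 thinnings each, so random loss of reads lowered it by less. Without keratinocytes 2 and 3, as an alternative chosen after seeing the data, 45 hairpins were higher and 147 lower, with the remaining keratinocyte library assumed to vary like the other groups.

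Enrichment in a cell type was counted where a hairpin was higher in both of its contrasts. Melanocytes had 5 enriched hairpins, hsa-mir-211, hsa-mir-508, hsa-mir-146a, hsa-mir-30d and hsa-mir-25, with the values above. Keratinocytes had 8: hsa-mir-205, hsa-mir-891a, hsa-mir-6087, hsa-mir-29c and hsa-mir-184, and, chosen after their values were seen, hsa-mir-1908 (30.6 ± 7.05 RPM against 2.3 ± 1.9 in fibroblasts), hsa-mir-375 (21.1 ± 12.6 against 0.177 ± 0.307 RPM) and hsa-mir-892a (35.6 ± 31.6 RPM against 0 fibroblast reads, at least 58.5-fold higher over the group). Fibroblasts had 3: hsa-mir-210 and, chosen after their values were seen, hsa-mir-1228 (6.56 ± 2.02 RPM against 0.461 ± 0.798 in keratinocytes) and hsa-mir-6511b-1 (3.32 ± 0.424 against 0.433 ± 0.388 RPM). For the fibroblast and keratinocyte hairpins, the contrast with melanocytes rested on 0 melanocyte reads, and only hsa-mir-205 and hsa-mir-210 had a mean above the limit of 875 RPM.

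The edgeR test gave 0 enriched hairpins in each cell type. With the replicate block the counts were 3 for melanocytes, 0 for fibroblasts and 1 for keratinocytes. The melanocyte count was 9 without keratinocyte 1 or melanocyte 1, 8 without melanocyte 2 and 3 without keratinocyte 2 or 3. The fibroblast count was 10 without keratinocyte 1, 1 without melanocyte 3 and 0 without any 1 of the fibroblasts, keratinocyte 2, melanocyte 1 or melanocyte 2. The keratinocyte count was 35 without keratinocyte 1, 5 without melanocyte 1 or 3, 2 without fibroblast 3, 1 without fibroblast 1 and 0 without fibroblast 2, keratinocyte 2 or melanocyte 2. With mock melanocytes 1 and 2 the counts were 38, 2 and 4 by limma and 69, 12 and 14 by edgeR.

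UVB at 10 mJ/cm2 was compared with mock exposure in melanocytes, and no hairpin passed the test. The melanocyte profile stayed led by hsa-mir-10b and hsa-mir-146a. Hsa-mir-10b averaged 228302 ± 47286 RPM in mock, 218666 ± 65989.5 in UVB 10 and 261986 ± 56387 in UVB 30 (n = 3 each). Hsa-mir-146a averaged 111819 ± 1879.7, 88303 ± 33152 and 112592 ± 6629 RPM. Hsa-mir-211 stood between 6354 and 15671 RPM across the 9 libraries.

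Limma called 0 of 406 hairpins for UVB 10 against mock, with 12 at an unadjusted p under 0.05 and a smallest adjusted p of 0.917, and edgeR called 0 of 268 with 8 (smallest adjusted p = 0.998). DESeq2 also called 0, with a median log2 fold change over hairpins of 1.11 against -0.46 by limma. The smallest p among higher values were those of hsa-mir-146b (log2 fold change 4.46, SE 1.93), hsa-let-7c (3.99), hsa-mir-155, a miRNA of immune activation (3.95), hsa-mir-31 (4.23) and the endothelial hsa-mir-126 (3.76). Among lower values they were those of hsa-mir-361 (-6.04, SE 2.20), hsa-mir-19a (-5.78), hsa-mir-146a (-0.43), hsa-mir-381 (-3.60) and hsa-let-7i (-0.47). In the 6 libraries of 1060966 or more reads, of which 1 was UVB 10, 2 of these 10 turned direction by limma, hsa-let-7c (-0.29) and hsa-mir-126 (-0.39). The log2 fold changes there were 0.22 for hsa-mir-146b, 0.53 for hsa-mir-155, 0.63 for hsa-mir-31, -0.25 for hsa-mir-361, -0.45 for hsa-mir-19a, -0.06 for hsa-mir-146a (0.07 by edgeR), -0.61 for hsa-mir-381 and -0.11 for hsa-let-7i, with the lone UVB 10 library assumed to vary like the other groups. Limma called 0 there (6 at an unadjusted p under 0.05) and edgeR 0 of 337 (4). Groups did not overlap for 15 hairpins (3.69%, against 10% by chance).

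Camera placed 3 lists up for UVB 10: let-7 and miR-98 (adjusted p = 0.00744, median 0.12), blood and endothelial miRNAs (adjusted p = 0.00744, median 0.94) and fibroblast and mesenchymal miRNAs (adjusted p = 0.0494, median -0.01, mean 0.22). With an estimated correlation their adjusted p were 0.449, 0.449 and 0.497. The other 4 lists tested had adjusted p of 0.855 each, and the keratinocyte and miR-17-92 lists had a direction of up with negative medians. In every list 0 members passed, by limma over all hairpins or over the list alone and by edgeR over all hairpins, of 25 p53 and DNA damage, 26 melanocyte, 11 keratinocyte, 22 fibroblast, 15 miR-17-92, 12 let-7, 3 14q32 and 5 blood and endothelial members. The count of 3 lists became 1 without mock 2, 0 without UVB 10 replicate 1 and 1 without UVB 10 replicate 3, and the let-7 direction turned to down in the 6 deep libraries (adjusted p = 0.676).

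At 30 mJ/cm2 against mock, too, 0 of 406 hairpins passed by limma, with 7 at an unadjusted p under 0.05 and a smallest adjusted p of 0.853. By edgeR 0 of 268 passed with 9 (smallest adjusted p = 0.665), and DESeq2 called 0. The DESeq2 median log2 fold change over hairpins was -3.48, against 0.88 by limma. The highest-ranked value was that of hsa-mir-200b, an epithelial miRNA that represses ZEB1 and ZEB2, with 2.66 ± 0.954 RPM (20 reads) in UVB 30 against 1 read in mock (log2 fold change 1.72, SE 0.51, adjusted p = 0.853). Hsa-mir-6840 averaged 3.45 ± 2.24 against 0.507 ± 0.475 RPM. Hsa-mir-3180-2 and hsa-mir-1272 had 0 mock reads, and their UVB 30 means were 2.36 and 2.18 times the 0.664 RPM that 0 reads allows in mock. These ratios do not cover the spread or counting error of the UVB 30 libraries, and neither hairpin passed. Hsa-mir-7704 had a log2 fold change of 1.11. Among lower values were those of hsa-let-7i (-0.37), hsa-mir-6509 (-0.76), hsa-mir-381 (-2.47), hsa-let-7f-1 (-0.36) and hsa-mir-92a-1 (-0.30). In the 6 deep libraries limma called 0 (15 at an unadjusted p under 0.05) and edgeR 0 of 337 (12). These fits did not pair the libraries by number, so differences between donors added to their error. Hsa-mir-381 turned direction there (0.28 by limma and 1.29 by edgeR), and the other 9 of these 10 values kept it by limma.

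No list was called by camera for UVB 30 against mock (adjusted p = 0.184 to 0.423), and 1 was without mock 2. Member counts over all hairpins were 0 in all 8 lists by limma and edgeR, and adjusted over the list alone 1 of 11 keratinocyte and epithelial miRNAs, hsa-mir-200b, was higher. In the 6 deep libraries that call ended (adjusted p over the list alone of 0.0584 by limma and 0.140 by edgeR). The p53, melanocyte, miR-17-92, let-7 and fibroblast lists had a direction of down with medians of 0.52, 0.39, 1.28, 0.18 and 1.03, beside a median of 0.88 over all hairpins. Groups did not overlap for 46 hairpins (11.33%, against 10% by chance). Without mock 3 the median over all hairpins was 0.01.

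Between doses, 0 of 406 hairpins passed by limma for UVB 30 against UVB 10, with 17 at an unadjusted p under 0.05 and a smallest adjusted p of 0.400, and 0 of 268 by edgeR with 6 (smallest adjusted p = 0.635). DESeq2 called 1 lower, hsa-mir-143. That fit had a median log2 fold change over hairpins of -4.66, opposite in sign to that of limma, so the call is uncertain. Hsa-mir-143 had 90 reads in UVB 10 replicate 3 (71485 RPM), and 5.99 to 23.4 RPM in UVB 30 (limma log2 fold change -5.09, SE 2.86, adjusted p = 0.4). Higher values with the smallest p were those of hsa-mir-200b (1.62), hsa-mir-6840 (1.82), hsa-mir-361 (5.71), hsa-mir-191 (0.38) and hsa-mir-5696 (1.72). Lower values were those of hsa-mir-21, a miRNA often raised in tumours (-0.53), hsa-mir-22 (-0.37), hsa-mir-127 (-4.02) and hsa-mir-1291 (-1.94). In the 6 deep libraries hsa-mir-143, hsa-mir-21, hsa-mir-22 and hsa-mir-127 turned direction, to 0.24, 0.11, 0.17 and 1.44 by limma and 0.41, 0.07, 0.12 and 2.05 by edgeR. Hsa-mir-361 fell to 0.12 there and hsa-mir-1291 stood at -0.74. The median over all hairpins was 1.26, but it was 0.54 without UVB 10 replicate 3, 2.08 without UVB 10 replicate 2 and 0.01 in the 6 deep libraries. Groups did not overlap for 57 (14.04%, against 10% by chance).

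Camera placed let-7 and miR-98 down between the doses (adjusted p = 3.25e-05, and adjusted p = 0.180 with an estimated correlation; median -0.07), a direction that turned to up with quantile normalization (adjusted p = 0.745) and in the 6 deep libraries (adjusted p = 0.368). It placed the fibroblast list down (adjusted p = 0.0274, and adjusted p = 0.556 with an estimated correlation) while its median and mean were 1.09 and 0.45. The count of 2 lists became 1 without UVB 10 replicate 2, UVB 10 replicate 3 or UVB 30 replicate 1. The p53, melanocyte, miR-17-92 and blood lists were not called (adjusted p = 0.421, 0.345, 0.345 and 0.224), with a direction of down and positive medians, and neither was the keratinocyte list (adjusted p = 0.737), of which 1 member, hsa-mir-200b, was higher when adjusted over the list alone. In the 6 deep libraries that call ended too (adjusted p over the list alone of 0.793 by limma and 0.928 by edgeR). Over all hairpins 0 members of any list passed by limma or edgeR.

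The responses to the doses were compared with each other. Log2 fold changes of UVB 10 and UVB 30 against the same mock libraries had a correlation across 406 hairpins, which are not independent replicates, of 0.403. Simulations drew all 9 libraries, mock included, anew from a common profile at their real depths, with the mock group shared by both doses. They gave 0.361 ± 0.0480 (SD, 100 simulations, 0.267 to 0.445). The real mock values were not kept in them. The covariance was 0.622 beside 0.494 simulated (0.323 to 0.644), and 42.4% of hairpins had the same sign beside 40.2% simulated. No hairpin was called at both doses (0 by limma, edgeR and DESeq2; independent lists would give 0), and the mock group is too small to give each dose its own controls of 2 libraries.

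Within the p53 and DNA damage list, hsa-mir-34c, a direct p53 target, was taken up after its values were seen. It stood at 4.71 RPM (95% interval 1.53 to 11.0) and 7.53 RPM (4.92 to 11.0) in mock 1 and 2, at 28.7 RPM (23.4 to 34.9) in UVB 10 replicate 2 and at 21.0 (16.6 to 26.3), 29.04 (22.3 to 37.2) and 13.2 RPM (8.29 to 20.02) in UVB 30. In the shallow libraries it had 0, 0 and 1 reads. Over all 9 libraries limma gave log2 fold changes of 2.97 at UVB 10 and 2.53 at UVB 30 (adjusted p = 0.917 and 0.853). In the 6 deep libraries edgeR gave 2.24 and 1.73 (adjusted p = 0.632 and 0.952, and 0.0450 and 0.0797 adjusted over the list alone), with 1 UVB 10 library. Limma gave 2.09 and 1.60 there (0.0638 and 0.0541 as adjusted p over the list alone).

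**Figure D4:**
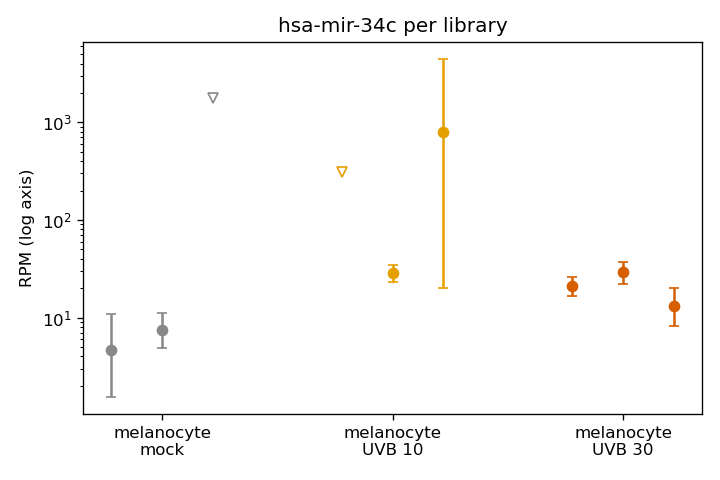
RPM of hsa-mir-34c in each melanocyte library of the UVB table (log axis), with exact 95% Poisson intervals as bars; open triangles mark libraries with 0 reads, drawn at the level of 3 reads. The 4 deep UVB libraries lie between 13.2 and 29.04 RPM, above mock 1 and 2 at 4.71 and 7.53 RPM.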

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

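The edgeR, DESeq2, 3-read filter, mock-melanocyte and left-out-library settings named as such in the methods were chosen after the results were seen, and the others before. Alternatives set for tables of counts did not apply, and a pseudocount of 0.01 was not tried. The cause of a change was not tested unless fewer hairpins or libraries account for it. Depth was a limit of the cell-type contrasts: 275 of 392 hairpins had 0 reads in the untreated melanocytes. Over all alternatives the counts for UVB stayed 0, except for 1 lower call between doses by DESeq2. For named hairpins 4042 of 4507 comparisons kept direction and side of the threshold, 204 lost a call, 45 gained 1, 190 turned direction with no call in either fit, named UVB hairpins in the 6 deep libraries among them, and 26 turned with a call in at least 1 fit. For lists these were, in the same order, 733, 69, 35, 80 and 16 of 933, and the correlation between doses moved in 12 of 22. All counts below are in the order higher, lower, for melanocyte against fibroblast (MF), melanocyte against keratinocyte (MK), keratinocyte against fibroblast (KF) and enriched in melanocytes, fibroblasts and keratinocytes, and counts not given stayed within 1.5 times. This does not hold for the median log2 fold changes.

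With the replicate block (paired by donor) MK higher fell to 3, KF was 1 and 0, and the enriched counts were 3, 0 and 1; no other count of calls moved by more than 1.5 times (MF 12 and 196, MK lower 91). With only the 2 groups compared KF was 2 and 1, and the median log2 fold change of all hairpins was -4.33 in MK. Without a filter MK higher was 3, KF 7 and 0, enriched melanocyte and fibroblast hairpins 3 and 0, and 5 lists were called in MK. The median was then -0.44 in MF and -0.56 in MK. A pseudocount of 0.1 gave 0 lower in KF and 0 enriched in fibroblasts. It moved the median to -5.60 in MF, -4.70 in MK, and 1.96 and 2.95 in UVB 30 against mock and against UVB 10. Quantile normalization, which forces all libraries to one distribution, gave MF 103 and 80, MK higher 102, KF 7 and 7, enriched 84, 5 and 3, and 2 lists each in MK and KF. It moved the median log2 fold change of all hairpins to 0.01, 0.01 and 0.00 in UVB 10 against mock, UVB 30 against mock and UVB 30 against UVB 10, and to -0.07 in KF. TMM scaling moved it to 0.99 and 1.38 in the UVB 30 contrasts, -3.12 in MF and -0.48 in KF. TMM scaling gave 1 list for UVB 10 against mock, and the filter of 5 RPM gave 2 lists in KF. By edgeR MF was 2 and 0, MK 0 and 0, and enriched 0, 0 and 0; with the replicate block MF was 1 and 0, MK 0 and 0, KF 4 and 1, and enriched 0, 0 and 0. DESeq2 gave MF 25 and 6, MK 2 and 1, KF lower 9, and enriched 2, 1 and 0. Its median log2 fold change of all hairpins with reads had the opposite sign to limma in all 6 contrasts. It was 5.05 in MF, 5.04 in MK, 0.99 in KF, 1.11 and -3.48 for UVB 10 and UVB 30 against mock, and -4.66 between doses. The DESeq2 counts, those of 0 for UVB included, are therefore weak evidence, and the cause was not tested. With the 30 hairpins worth 3 reads in the shallowest library, MF was 6 and 1, MK 2 and 2, KF 3 and 0, enriched 2, 0 and 1, and 0 lists in all contrasts. Mock melanocytes gave by limma MF 64 and 78, MK 46 and 55, enriched 38 and 4 in melanocytes and keratinocytes, and 4 lists in MK. By edgeR they gave MF 91 and 125, MK higher 79, KF 20 and 15, and enriched 69, 12 and 14. Without keratinocytes 2 and 3 KF was 45 and 147, and enriched 2, 144 and 38.

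Leaving out each library gave 12 to 16 higher and 145 (fibroblast 3) to 237 (keratinocyte 1) lower in MF. It gave 3 (keratinocyte 2) to 9 (keratinocyte 1) higher and 89 to 246 (keratinocyte 1) lower in MK, and 0 (fibroblast 2) to 38 higher and 0 (fibroblast 1) to 10 lower in KF, both without keratinocyte 1. Enriched counts were 3 to 9, 0 to 10 and 0 to 35. Lists called were 0 to 3 and 0 to 1 against mock, 1 to 2 between doses, 2 to 3 in MF, 1 to 3 in MK and 1 (keratinocyte 1) to 6 (keratinocyte 2) in KF.

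All list calls were lost with an estimated correlation (0 lists in every contrast). Fry, which asks whether the members move together and not whether they differ from other hairpins, counted 0 lists in the UVB contrasts and KF, 6 in MF and 7 in MK. In the UVB contrasts its p also moved with the order in which the groups entered the fit. Its direction was opposite to camera for the fibroblast list at UVB 10 (adjusted p = 0.996) and between doses (0.416), in MF for the p53 list (5.24e-05), keratinocyte list (0.0377), miR-17-92 (0.000339) and let-7 (0.427), and in MK for the melanocyte list (0.170), miR-17-92 (0.000194) and let-7 (0.0494). The let-7 direction also turned with quantile normalization between doses (0.745) and in MF (0.385), with the 3-read filter in MF (0.998), with mock melanocytes in MF (0.606), and without the 3 shallow UVB libraries at UVB 10 (0.676) and between doses (0.368), where 0 lists were called, as with quantile normalization. The 14q32 direction in KF turned without keratinocyte 1 (0.630), and the lowest adjusted p of that list was 0.00541 without keratinocyte 2.

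With mock melanocytes 89 of the 209 lower hairpins in MF and 35 of the 93 in MK turned to higher in melanocytes by limma. Among the named hairpins the log2 fold change turned, by limma and then edgeR, in MF for hsa-mir-192 (1.80, 1.33), hsa-mir-29b-1 (1.59, 1.14), hsa-mir-106b (1.24, 0.77), hsa-mir-19a (0.97, 0.52), hsa-mir-93 (2.81, 2.30) and hsa-mir-126 (2.20, 1.63). In MK it turned for hsa-mir-192 (0.28, 0.13), hsa-mir-29b-1 (0.86, 0.98), hsa-mir-106b (1.00, 1.01), hsa-mir-19a (0.96, 0.83), hsa-mir-93 (2.02, 1.89), hsa-mir-126 (3.14, 1.98) and, by limma, hsa-mir-342 (0.0495). Hsa-mir-126 turned to 2.80 in KF without keratinocytes 2 and 3.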

Other observations

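The comparisons with mock melanocytes, the tests of keratinocytes 2 and 3 and those of hsa-mir-34c were chosen after the results were seen, and the thinning of libraries and the counts of other splits were set before. The imprinted miRNAs of chromosome 14 took few reads in the deep melanocyte libraries, but not in every shallow one. The list took 0.00245% and 0.000811% of reads in mock 1 and 2, against 3.51% to 4.13% in fibroblasts, 1.54% in keratinocyte 1 and 9.96% and 9.91% in keratinocytes 2 and 3. It took 0.000939% to 0.00697% in the 4 deep UVB libraries, but 0.299%, 0.0207% and 1.91% in the shallow mock 3, UVB 10 replicate 1 and UVB 10 replicate 3, and 6.84%, 1.56% and 0% in untreated melanocytes 1, 2 and 3. The share in untreated melanocyte 1 was above that of fibroblasts, and why it differed between melanocyte libraries was not tested. Against keratinocytes, with mock melanocytes 1 and 2, 18 of 45 members were lower by limma (camera adjusted p = 2.34e-16, and adjusted p = 0.348 with an estimated correlation) and 41 of 41 by edgeR. Melanocyte-list miRNAs were higher than in fibroblasts for 10 of 18 members by limma and lower for 4, with 19 and 4 of 27 by edgeR.

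Hsa-mir-143 had 0 to 90 reads in the melanocyte libraries: 8, 23 and 7 in mock, 1, 34 and 90 in UVB 10, 39, 13 and 39 in UVB 30 and 17, 27 and 0 in untreated melanocytes, against 339003, 519508 and 115569 in fibroblasts. In RPM this gave 7.54 and 6.66 in mock 1 and 2 but 71485 in UVB 10 replicate 3 and 52734 in untreated melanocyte 2.

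The first pattern weighed was the excess of lower calls in untreated melanocytes, 209 against fibroblasts and 93 against keratinocytes. When fibroblast libraries were thinned at random to the 3 melanocyte depths and set against the full fibroblast libraries, a median of 188 hairpins was called lower (170 to 205 over 100 thinnings, 165 of them shared with the real calls) and 0 higher; thinned keratinocytes gave 72 (60 to 84, 57 shared). The values are consistent with depth alone giving most of the lower calls in both contrasts, and edgeR gave a median of 0 for both. Truly lower levels account for part of them at most: with mock melanocytes, by limma, 89 of the 209 turned sign, 55 were called lower again, hsa-mir-493 and hsa-mir-214 among them, and 19 were called higher, hsa-mir-192 among them, while the others stay open.

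The second pattern was the fibroblast-like profile of keratinocytes 2 and 3. Fibroblast material or reads as the only source of their 14q32 reads are argued against by the 14q32 list, whose members stood at medians of 1.23 and 1.53 times the same-numbered fibroblast library while hsa-mir-143 stood at 0.0953 and 0.163 times, ratios of 13.0 and 9.39 between the list and hsa-mir-143. These ratios cannot exclude a smaller part of fibroblast material, since hsa-mir-143 was at 20832 and 27937 RPM in them and at 619 RPM in keratinocyte 1. An exchange of labels with fibroblasts is argued against by hsa-mir-205, which reached 1.48 RPM at most in fibroblasts and 68534 RPM in keratinocyte 1. Since both libraries had the profile, 1 wrong label does not account for it, while wrong labels of both, a part of fibroblast material, cells of another mesenchymal type and a culture difference between donors stay open and were not tested. 

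The third pattern was hsa-mir-34c, at a mean of 6.12 RPM in mock 1 and 2 and 23.0 RPM in the 4 deep UVB libraries. Counting error alone is argued against by the pooled reads, 31 of 4515167 against 262 of 10958993 (rate ratio 3.48, 95% interval 2.39 to 5.23, exact binomial p = 2.94e-14). That p takes reads as replicates and does not bear on UVB. Libraries of 1 group also differed beyond counting error, with a chi-square per degree of freedom over hairpins of 271 between mock 1 and 2. Reads from the fibroblasts or keratinocytes 2 and 3, the libraries of those types with over 100 hsa-mir-34c reads, are argued against by the ratio of hsa-mir-34c to hsa-mir-199a-1 reads, 0.431 or more in each of these UVB libraries and 0.175 at most in those sources, and keratinocyte 1, with 6 hsa-mir-34c reads, held 1992 of hsa-mir-205 where the 4 UVB libraries held 0 to 7. Chance in the order of the 6 libraries stays open, with an exact two-sided permutation p of 0.133, where 15 splits allow no p under 0.0667, and of 0.167 within same-numbered libraries, where all 3 UVB libraries with a deep mock partner were higher and 6 arrangements allow no smaller p. An induction of the p53 target by UVB may account for the pattern and is a hypothesis, since no list member passed over all hairpins and the hour of harvest was not known.

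Other splits of the libraries into the same group sizes were fitted in the same way. With 10 splits of 3 against 3 libraries, the real one counted among them, a share under 0.05 cannot be reached. For calls the real and the highest other count were 0 and 203 for UVB 10 against mock, 0 and 0 for UVB 30 against mock, 0 and 1 between doses, 222 and 0 for melanocytes against fibroblasts, 98 and 3 for melanocytes against keratinocytes, and 14 and 1 for keratinocytes against fibroblasts. As many calls as the real count came in 10, 10, 10, 1, 1 and 1 of the splits. For lists the pairs were 3 and 2, 0 and 2, 2 and 1, 3 and 3, 1 and 4, and 4 and 5, with as many in 1, 10, 1, 5, 10 and 6 splits. Over 100 splits, the real grouping among them, the highest other counts beside the 5, 3 and 8 enriched hairpins of melanocytes, fibroblasts and keratinocytes were 0, 1 and 4. Only the real grouping itself reached as many. In the 2 contrasts with untreated melanocytes, only the real grouping kept the 3 shallow melanocyte libraries together. Those splits therefore do not tell cell type from depth. In the contrast of keratinocytes and fibroblasts every split kept them together. How many of the splits drawn for the enriched counts did so was not counted, so those do not settle it either. For shared UVB calls the real count was 0, which every one of the 100 splits reaches (highest other 188), so that count was not tested by them. The 203 and 188 calls came from splits other than the real one. Among the 10 splits of UVB 10 and mock libraries, 1 set the 3 libraries of under 10000 reads against 3 deep ones. Which splits gave those calls was not recorded, so depth is a possible cause that was not tested.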
